A study of Mus musculus with 4 samples.

How the data were processed

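Genomic DNA from mouse small-intestinal tumour organoids was hybridised against kidney DNA on 4 Agilent comparative genomic hybridisation arrays, 1 array per sample. Per the labels, the organoid DNA carried Cy5 and the kidney DNA of a young healthy Bl6 mouse carried Cy3, with no dye swap, and both were labelled male. The labels' labelling protocol names liver as the tissue of both channels, whereas the source and extraction fields name tumour organoids and kidney; the latter are used here. Per the labels' protocols, 1 µg of DNA was labelled by random priming after 4 days of doxycycline at 0.5 µg/ml, which switched on the hairpins. Groups came from the labels: 1 array of organoids with the control hairpin and 3 arrays of organoids with hairpin 2 against Suv4-20h2, directed at exon 9. The hairpin against exon 4 was not analysed here. No label says that the 3 knockdown samples came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

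The deposited scanner files hold spot intensity in each channel, read with Agilent Feature Extraction version 10.7.3.1 per the file headers and version 12.0.0 per the submitters' processing notes. Per the file headers, the authors' processed intensity is background-subtracted with spatial detrending and scaled with 1 linear dye factor per channel, and the array design uses mouse build mm9 (NCBI37). The deposited log10 ratio is Cy5 over Cy3 of these processed signals. The series' value table held the same log10 ratios, with a largest difference of 0 from the scanner values on all 4 arrays. Its scale, centring and direction are therefore known, and its column medians were -0.000919 for the control and -0.00319, -0.00248 and -0.00209 for knockdown 1, 2 and 3.

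Each array had 180880 spots, of which 174305 were not controls. Spots with outlier flags were removed, 85 on the control array and 114, 118 and 128 on the knockdown arrays. Saturated spots were kept; there were 0, 12, 11 and 1 of them in the same order. Spots of 1 probe were averaged, which left 170305 probes, and the log2 ratio of processed Cy5 to processed Cy3 was centred on each array's median. Because large parts of the genome were gained, this centring put unaltered autosomes slightly below 0. No loess or quantile step was used, since most probes carry signal and many can shift in a single direction. In 2 copies, the gain of 1 copy in every cell gives a log2 ratio of 0.585 and the loss of 1 copy gives -1. All 4 arrays lay on 1 slide in 1 scan, so no batch could be tested. No 2 files held identical values.

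The array design's gene names were used, 18703 in all. Of these, 15427 matched a symbol and 712 a synonym in a RefSeq gene table of another build, which served only for names and gene order; 4 matched several genes and 2560 none, and those kept the design's name. A gene name covered 103071 probes, and 67234 probes had only a coordinate. Coordinates are those of the files, in mm9, counted from 1.

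Log2 ratios were averaged over 1 Mb windows with at least 10 probes and over genes with at least 3 probes. limma (version 3.58.1, R 4.3.3; files read with data.table, version 1.17.8) fitted the 4 arrays with 1 mean per group, followed by empirical Bayes moderation. Knockdown minus control and the knockdown mean against 0, which compares organoids with kidney, were called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 value of at least 0.1. The lone control is assumed to vary like the knockdown arrays, and the comparison with kidney leaves out the spread of the reference itself. Standard errors (SE) are limma's; SDs are over the 3 knockdown arrays. Chromosome means and chromosome ends had 1 value per array and a two-sided exact permutation test over the 4 choices of the lone array, whose smallest p is 0.25. Each array was also divided into segments by recursive circular binary segmentation, with a split kept at a t statistic of at least 6; a segment was altered with at least 5 probes and an absolute mean of at least 0.2. Signals not well above background give only a bound: the kidney level over the higher of the organoid signal and the lowest signal well above background on that array. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

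Before the data were examined, these settings, the alternatives other than the joining of segments, 10 gene lists and the rule for named genes were fixed. The rule names the targeted gene, its paralog, Apc, Trp53 and Tgfbr2 where they had at least 3 probes; 1 further gene of this rule and the count of the list of genes the letters APT may stand for are not reported here. Per comparison and list it names up to 3 called members of largest size, or the largest member where none was called. It also names the 5 regions of merged called windows of largest mean per direction, with the 3 genes of most probes in each, and per array the 3 longest and 3 largest altered segments per direction. The lists were the targeted gene and paralog, genes the letters APT may stand for, heterochromatin and H4K20 methylation, intestinal tumour genes, amplified oncogenes, deleted tumour suppressors, large genes at common fragile sites, DNA repair with mitosis and cohesin, loci that vary between mouse strains, and antigen receptor loci. The last had 0 members with enough probes and gave no result.

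The steps were tested on simulated data. For windows and genes, every array received normally distributed noise sized from the spread between the knockdown arrays. The control was thus taken to vary like them, and no single probe parted between arrays beyond this noise. Segments were planted on flat chromosomes with noise independent between probes. False calls may therefore be more frequent in the real data. For windows, knockdown minus control, 49 of 50 planted differences of 0.12 and all 50 of 0.2, 0.3 and 0.58 were recovered among 2534 windows, with 0 false calls. For genes, 28 of 50 differences of 0.12, 48 of 50 of 0.2 and all 50 of 0.3 were recovered among 8742 genes, with 3 false calls. Planted segments of 0.3 were found in 10 of 19 cases with 5 probes and 18 of 19 with 10 probes; segments of 0.58 or -1 were found in all 19 cases at each length.

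The alternatives were normexp background correction (offset 50), mean signal minus background, centring on the density mode, removal of a GC trend, probes well above background on all arrays, no flag filter, the value table, each knockdown array left out, other window sizes and probe minimums, medians, other thresholds, and other segment and end settings. The number of arrays limits the precision of every group value.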

Results

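Copy number was measured in tumour organoids, miniature tissue cultures of small-intestinal tumour cells, named APT by the submitters, who do not spell the letters out. The design asks what depletion of Suv4-20h2 does in these organoids; this enzyme, now called Kmt5c, adds methyl groups to lysine 20 of histone H4. There were 3 knockdown arrays and 1 control array, each set against kidney DNA. Probes lay a median of 10878 bp apart, with 8723 on X and 122 on Y. The spread between neighbouring probes was 0.115 log2 on the control array and 0.119, 0.114 and 0.124 on the knockdown arrays. The signal-to-noise ratio was 181 to 190 for Cy5 and 196 to 232 for Cy3, and at least 99.955% of Cy5 spots were well above background. Over 2534 windows, Pearson's r between knockdown arrays was 0.996 to 0.998, and between a knockdown array and the control 0.977 to 0.981; windows are not independent replicates.

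The targeted gene had 0 probes named for it. The 5 probes from its neighbour Tmem150b to its neighbour Fam71e2, on chromosome 7 from 4674882 to 4718843, averaged 0.038 in the control and 0.026 ± 0.024 (SD, n = 3) in the knockdown. The 1 Mb window around them, with 95 probes, differed by -0.02 ± 0.0083 (SE; limma adjusted p = 0.135). A hairpin lowers RNA and leaves the gene in place, so a copy number array cannot show whether the knockdown worked. The paralog Kmt5b, on chromosome 19 and named Suv420h1 in the array design, had 5 probes. It averaged -0.076 in the control and -0.04 ± 0.022 (SD, n = 3) in the knockdown, a difference of 0.04 ± 0.024 (SE; adjusted p = 0.432).

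Against kidney DNA, both organoid groups carried gains of all of chromosomes 5 and 12 and of the first part of X, and had almost no Y signal. Chromosome 5 averaged 0.53 ± 0.0048 (SD, n = 3) in the knockdown and 0.44 in the control, and chromosome 12 averaged 0.51 ± 0.0037 and 0.44. All 147 windows of chromosome 5 and all 113 of chromosome 12 were called higher in the knockdown. Chromosome 5 holds the cell-cycle kinase gene Cdk6, the receptor tyrosine kinase genes Kit and Pdgfra, the Mediator kinase gene Cdk8 and the DNA repair gene Brca2. Chromosome 12 holds Dnmt3a, a de novo DNA methyltransferase, and the signalling kinase gene Akt1. The remaining 13 autosomes, all except 4, 5, 12, 13, 14 and 19, averaged between -0.046 and -0.023 in the knockdown and between -0.041 and -0.0012 in the control.

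**Figure D1:**
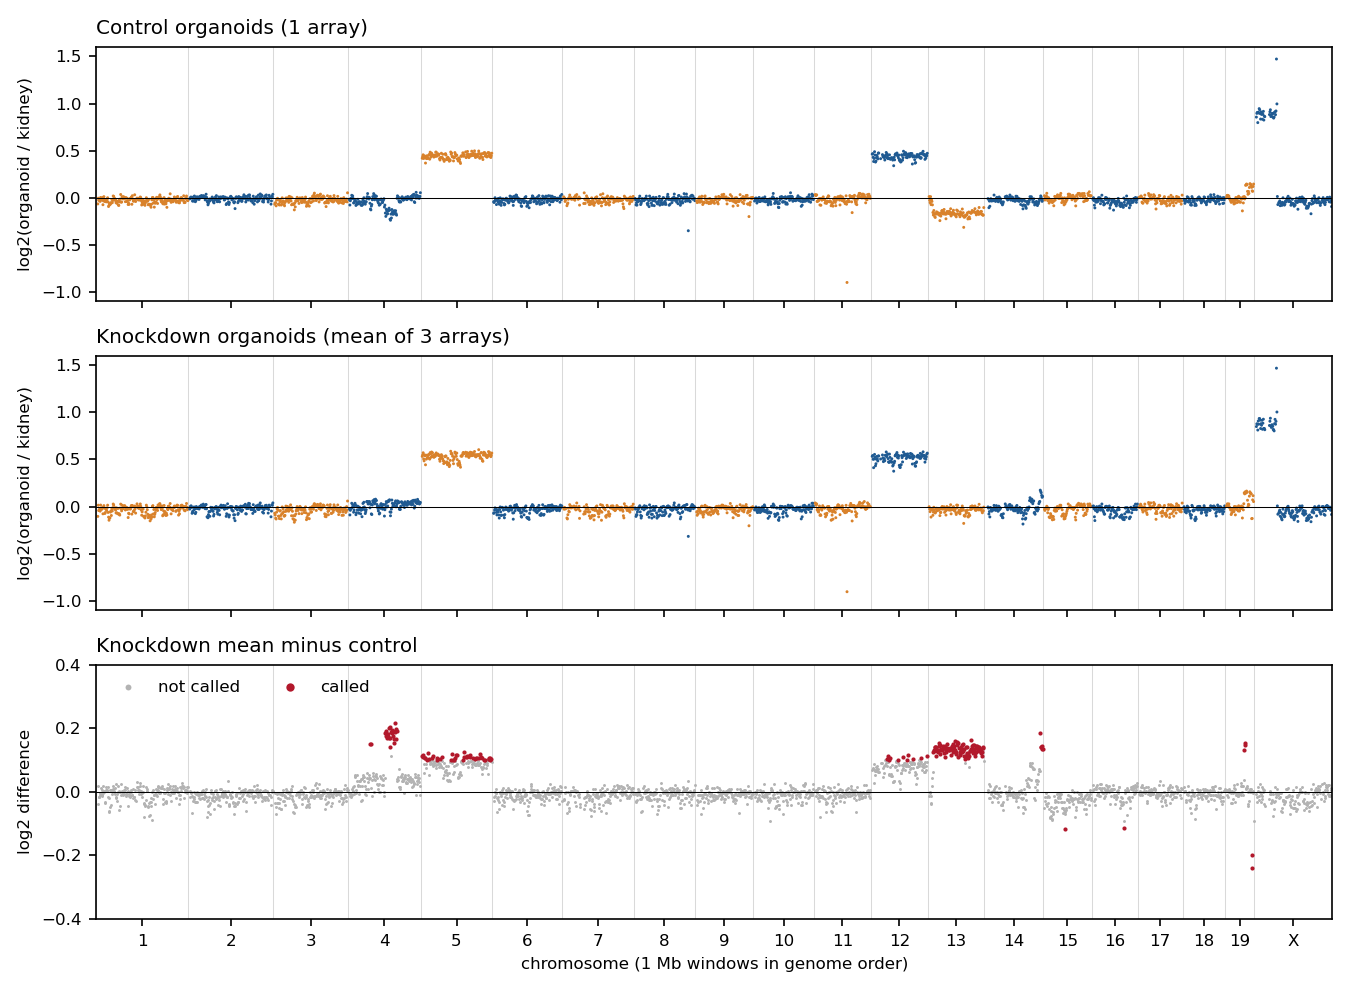
Log2 ratio of organoid to kidney DNA in 1 Mb windows along the genome (mm9, Y left out) for the control array (top) and the mean of the 3 knockdown arrays (middle), with the difference of both and its called windows in red (bottom). Chromosomes 5 and 12 and the start of X lie above the rest in both groups, and the red windows lie mainly on chromosomes 4, 5, 12 and 13.

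Of 2534 windows, limma called 506 in the knockdown against kidney, 314 higher and 192 lower (62.1% higher). With normexp the split was 316 and 318 (49.8% higher), and with mode centring 316 and 131 (70.7% higher). Lower calls were also fewer without knockdown replicate 3. Their number thus depends on the background correction, the centring and the arrays used. Most lower calls were shallow: with a minimum size of 0.2 there were 296 higher and 6 lower, and with none 564 and 1361 (29.3% higher). The 5 largest gained regions were X from 33000001 to 50000000 (Tenm1, Gpc3 and the transcript ENSMUST00000144412, with the cohesin gene Stag2), X from 5000001 to 24000000 (Cask, Shroom4 and Efhc2, with Kdm6a and Suv39h1), chromosome 5 from 96000001 to 153000000 (Auts2, Sdk1, Tmem132d) and from 3000001 to 94000000 (Magi2, Dpp6, Adgrl3), and chromosome 12 from 25000001 to 122000000 (Nrxn3, Immp2l, Npas3). Their knockdown means over probes were 0.93, 0.88, 0.55, 0.53 and 0.52, and the control's 0.94, 0.89, 0.46, 0.44 and 0.44. The largest adjusted p of a called window in these regions was 1.84e-06. The 4 gained regions outside these chromosomes were smaller: chromosome 19 from 41000001 to 48000000, 52000001 to 57000000 and 60000001 to 61000000, and chromosome 14 from 120000001 to 126000000, with knockdown means of 0.15, 0.14, 0.12 and 0.14.

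**Figure D2:**
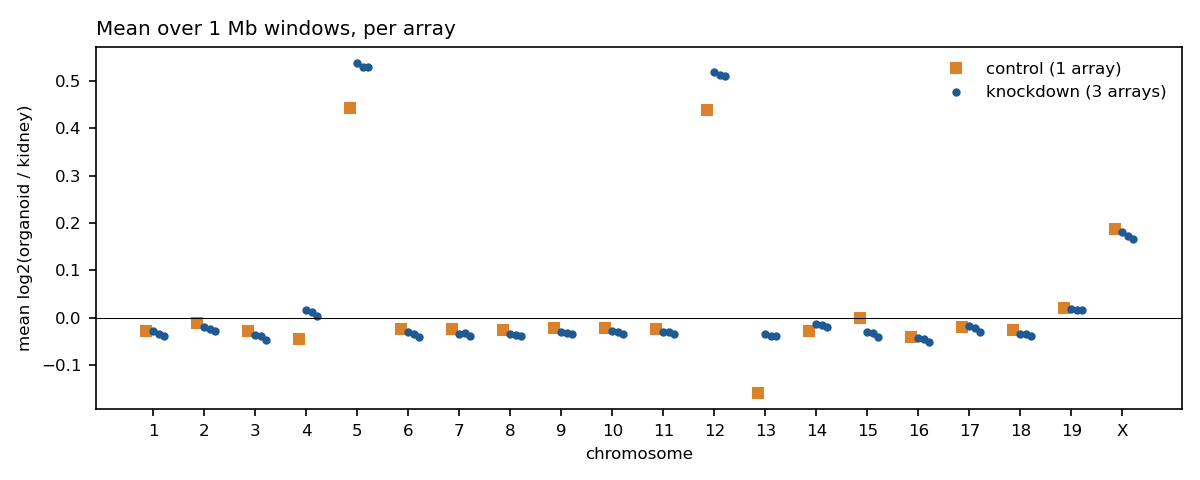
Mean log2 ratio of organoid to kidney DNA over the 1 Mb windows of each chromosome (Y left out), with 1 square for the control array and 1 circle for each of the 3 knockdown arrays. The knockdown arrays lie at about 0.53 on chromosome 5 and 0.51 on chromosome 12, above the control at 0.44 on both.

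On X the gain ended at 1 position on all 4 arrays. From 4990184 to 47929670 (1918 probes) the ratio to kidney was 1.83 in the knockdown (log2 0.87 ± 0.009, SD, n = 3) and 1.85 in the control (0.89). The adjoining stretch from 47945902 to 49744504 (139 probes), which holds Hs6st2 and the glypican genes Gpc3 and Gpc4, stood higher, at a ratio of 2.80 in both groups (log2 1.49 ± 0.0015 in the knockdown). From 49751352 to the end of the array's X probes, the mean was -0.05 ± 0.0059 in the knockdown and -0.04 in the control. Kdm6a, an H3K27 demethylase gene, was at 0.91 ± 0.012 (SE) and Stag2 at 0.90 ± 0.012, each with an adjusted p of 2.14e-07. Neither differed between groups by the test (adjusted p = 0.788 and 0.251).

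**Figure D3:**
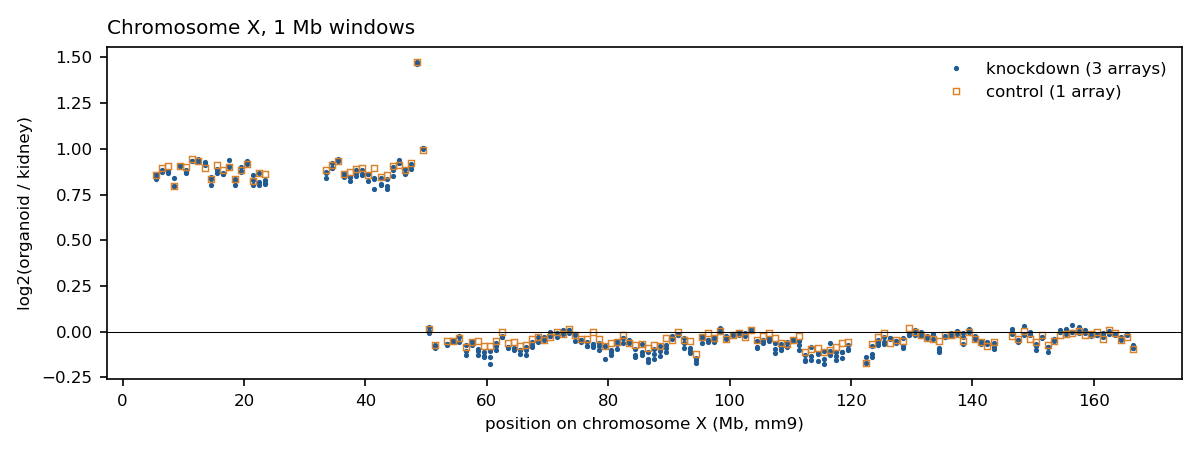
Log2 ratio of organoid to kidney DNA in 1 Mb windows along chromosome X (mm9) for the control array (open squares) and the 3 knockdown arrays (dots). Both groups lie near 0.9 up to about the position 47929670, higher from there to 49744504 and near 0 after it.

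Chromosome Y, with Uty, Usp9y and Kdm5d, averaged -3.81 ± 0.064 (SD, n = 3) over its 3 windows in the knockdown and -3.80 in the control, although both channels are labelled male. Of the 122 probes, 55 were not well above background on every knockdown array and 59 on the control array. These were at least 15.2-fold lower than kidney in the knockdown (median; 2.17 to 52.1 over probes) and at least 18.6-fold lower in the control. The 67 and 63 measured probes had medians of -3.37 and -3.36. With normexp, which adds an offset to both channels, the mean of Y was -1.42. The exact permutation p for Y between groups was 1, and for the X mean, 0.17 against 0.19, it was 0.5.

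The other low regions were short. The window of chromosome 11 from 71000001 to 72000000 averaged -0.90 ± 0.022 (SD, n = 3) in the knockdown and -0.90 in the control. Across its start, 11 probes from 70989862 to 71107103 covered Nlrp1b, an inflammasome sensor gene, and the pseudogene Nlrp1c-ps; 3 of them in the knockdown and 5 in the control were not well above background, with a median bound of at least 44.4-fold and 36.0-fold below kidney (lowest 19.2-fold and 22.3-fold). A window on chromosome 9 from 115000001 to 116000000 (Gadl1, Osbpl10, Stt3b) stood at -0.20 ± 0.011, and chromosome 14 from 82000001 to 84000000, with no named gene, at -0.16 ± 0.026. With the median over probes in place of the mean, the windows on chromosomes 11 and 9 lay at -0.08 and -0.085 and were no longer called, so few probes set their means. The window of chromosome 8 from 117000001 to 118000000 was at -0.32 ± 0.0056 and is filled by Wwox, a large gene at a common fragile site; with the median it lay at -0.117 and was still called.

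Within Wwox the segments of the groups differed in depth. From 117308196 to 117365094 (7 probes) the control stood at -1.44 and the knockdown at -1.04 ± 0.0081 (SD, n = 3). From 117405444 to 117559185 (16 probes) the order turned, with -0.73 in the control and -0.98 ± 0.024 in the knockdown. Over the whole gene the difference was 0.03 ± 0.019 (SE; limma adjusted p = 0.458), which hides both. A depth difference also stood on chromosome 13, all of which averaged 0.12 lower in the control, from 77642127 to 77735940 (10 probes, 2210408I21Rik), at -1.32 in the control and -1.01 ± 0.042 in the knockdown. These differences between segments were not tested.

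**Figure D4:**
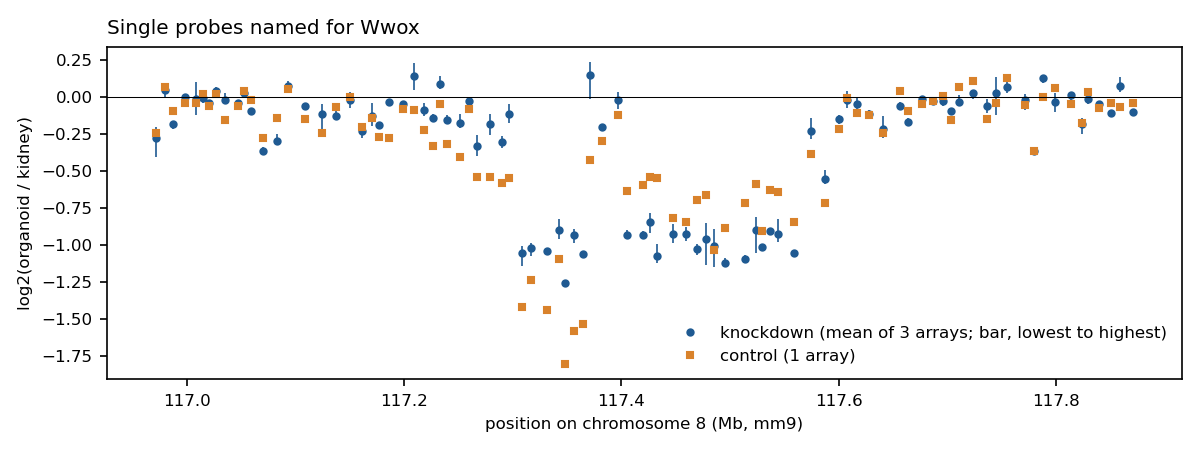
Log2 ratio of organoid to kidney DNA at the single probes named for Wwox on chromosome 8 (mm9), for the control array (squares) and the knockdown mean (circles; bars run from the lowest to the highest of the 3 arrays). Between 117308196 and 117365094 the control lies lower. Between 117405444 and 117559185 the knockdown lies lower on average, though not at the probe at 117485482.

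Among genes with at least 3 probes, 1791 of 8740 were called in the knockdown against kidney, 1317 higher and 474 lower, including all 573 tested genes of chromosome 5 and all 329 of chromosome 12. With normexp there were 869 lower genes. Of 16 amplified oncogenes tested, 4 were called higher, Cdk6 (0.49 ± 0.011, SE), Cdk8 (0.64 ± 0.010), Pdgfra (0.57 ± 0.012) and Kit, all on chromosome 5. Of 20 genes of DNA repair, mitosis and cohesin, 6 were called higher: Brca2 (0.68 ± 0.012), the checkpoint kinase gene Chek2 (0.63 ± 0.011), Stag2, Bub1, Mad1l1 and Smc3. Of 17 tumour suppressors, Brca2, Chek2 and Kdm6a were called higher and Tgfbr1 lower. Of 21 large fragile-site genes, Auts2 (0.48 ± 0.011), Immp2l (0.49 ± 0.0094) and Magi2 (0.51 ± 0.0096) were called higher and Csmd1, Lrp1b, Nbea and Wwox lower. Apart from Wwox these lower values were shallow (-0.114, -0.113 and -0.101). Separately, windows with few gene probes read lower over the 11 autosomes with no window called between groups. Spearman's correlation of window value with the share of gene probes was 0.29 in the control and 0.30, 0.30 and 0.33 in the knockdown arrays. The windows poorest in gene probes averaged -0.052, -0.058 and -0.071 in the knockdown arrays, and the richest -0.024, -0.027 and -0.030. Even the poorest thus stood less low on average than Csmd1, Lrp1b and Nbea. Whether this trend lowers these genes was not tested. Of 10 heterochromatin genes, 1 was called, Dnmt3a (0.49 ± 0.0093). The adjusted p of each of these genes was at most 0.00419, and the counts adjusted over the list alone were the same.

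Of 23 intestinal tumour genes, 3 were called higher, none on chromosome 5, 12 or X: Axin2, a Wnt feedback gene, at 0.22 ± 0.011 (SE; adjusted p = 1.37e-05), the Wnt transcription factor gene Tcf7l2, within the gained region of chromosome 19 from 52000001 to 57000000, at 0.13 ± 0.0098 (adjusted p = 0.00014), and Smad2. Over alternatives Axin2 lay between 0.1238 and 0.2325 and kept its call. The TGF-beta receptor gene Tgfbr2 was called lower, at -0.26 ± 0.012 (adjusted p = 1.03e-05) in the knockdown and -0.32 in the control. Only 2 of its 9 probes carried this, at 116012723 (-2.11 ± 0.027, SD, n = 3) and at 116050144 (-0.91 ± 0.060), and the median over its probes was 0.07 with an adjusted p of 0.0131 (range over alternatives 7.15e-07 to 0.0131). Apc, a negative regulator of Wnt signalling, was at -0.03 ± 0.0093. Trp53 had only 2 probes, at 0.16 and 0.14 in the knockdown, and was not tested. Of 10 loci that vary between mouse strains, 3 were called lower: Nlrp1b (-3.85, an inexact value, since 4 of its 6 probes had almost no organoid signal; range over alternatives -4.331 to -2.141), the insulin-degrading enzyme gene Ide (-0.54 ± 0.010) and Cd244a (-0.11 ± 0.019, adjusted p = 0.00486). The call of Cd244a was lost without knockdown replicate 3 (-0.09), and the median over its probes was 0.022 (adjusted p = 0.325; range over alternatives 0.00038 to 0.979). Adjusted over the list alone, the counts for these 2 lists were the same.

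Between the groups, the question was whether copy number differed with the knockdown. The largest part of the difference lay on chromosome 13, on a region of chromosome 4, and in the size of the gains of chromosomes 5 and 12. Chromosome 13 averaged -0.16 in the control and -0.04 ± 0.0025 (SD, n = 3) in the knockdown, close to the unaltered chromosomes. Chromosome 4 from 80000001 to 105000000, which holds Nfia, Fggy and Adamtsl1, the cell-cycle inhibitor gene Cdkn2a and Dab1, averaged -0.16 in the control and 0.025 ± 0.0026 in the knockdown. Relative to the unaltered autosomes, this region lay at -0.139 in the control and 0.050 in the knockdown. Part of its difference was thus a raised knockdown value. The gains of chromosomes 5 and 12 were larger in the knockdown by 0.09 and 0.08. All 3 knockdown arrays lay on the same side of the control in each of these. They also did so on most other chromosomes, such as 2, 3 and 15, so the side alone does not set these apart.

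By limma, 201 of 2534 windows were called, 197 higher and 4 lower in the knockdown, with 514 at the adjusted p alone and a median difference of -0.0026. Higher calls were 105 of 117 windows on chromosome 13, 46 of 147 on 5, 26 of 152 on 4, 11 of 113 on 12, 6 of 115 on 14 and 3 of 59 on 19. The called windows formed 33 higher and 3 lower regions. Beyond the 5 of largest mean, the higher regions all lay on chromosomes 5 and 12. There the mean difference of the whole chromosome, 0.088 and 0.076, lay just below the size minimum of 0.1. The number of regions therefore does not count separate changes. The mean of the called windows was 0.18 in the region of chromosome 4 (24 windows, adjusted p 0.000418 to 0.00599). It was 0.15 on chromosome 4 from 48000001 to 50000000 (Plppr1, Grin3a, Invs), and 0.13 on chromosome 13 from 12000001 to 120000000 (Pde4d, Sugct and Mast4, with Ptch1 and Tert; adjusted p up to 0.017). Chromosome means differed by 0.12 on chromosome 13, 0.088 on 5, 0.076 on 12 and 0.055 on 4, each with an exact permutation p of 0.25, the smallest that 4 arrays allow. Chromosomes with small differences, such as 2 (-0.014) and 3 (-0.013), reached this smallest value too, so it does not set these chromosomes apart. Setting 1 control against 3 samples of 1 hairpin, the design cannot tell the hairpin from differences between cultures. The count of called windows rose to 313 with normexp and was 4 with a minimum size of 0.2.

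**Figure D5:**
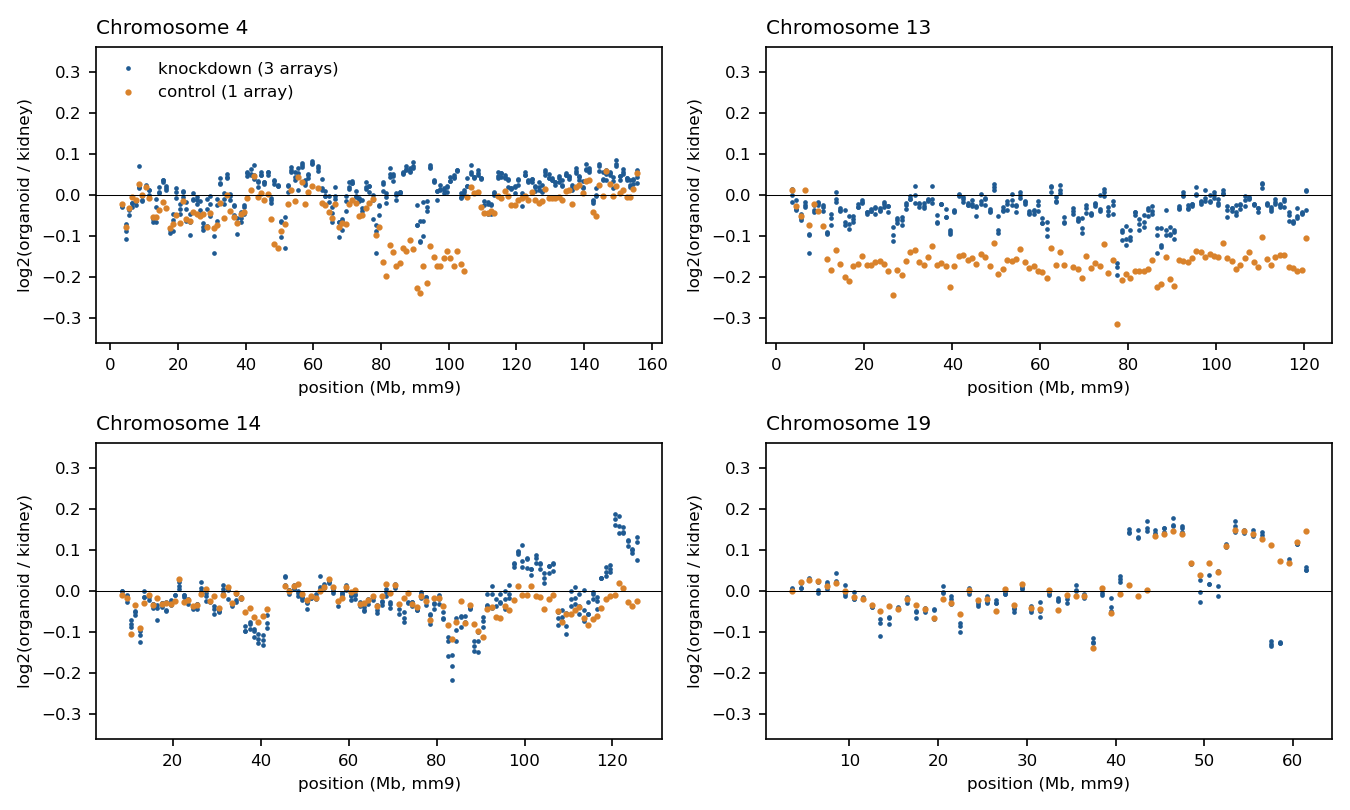
Log2 ratio of organoid to kidney DNA in 1 Mb windows along chromosomes 4, 13, 14 and 19 (mm9) for the control array and the 3 knockdown arrays. The control lies below the knockdown along chromosome 13 and on chromosome 4 from 80000001 to 105000000, and the arrays part in the opposite way on chromosome 19 from 57000001 to 59000000.

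Other differences lay in shorter regions. Chromosome 14 from 120000001 to 126000000, which holds the fibroblast growth factor gene Fgf14, Pcca and the sodium leak channel gene Nalcn, averaged 0.14 ± 0.008 (SD, n = 3) in the knockdown and -0.011 in the control. Chromosome 19 from 41000001 to 44000000 (Hpse2, Crtac1, Tll2) averaged 0.15 ± 0.0092 and 0.0018. The largest lower region was chromosome 19 from 57000001 to 59000000, with Atrnl1, the GDNF receptor gene Gfra1 and Ablim1. It averaged -0.13 ± 0.0039 in the knockdown and 0.093 in the control, a difference of -0.22 over 2 windows (limma adjusted p = 0.000418 for both). The other 2 lower regions were 1 window each: chromosome 15 from 46000001 to 47000000 (4930523O13Rik, 1700022A22Rik; -0.12 ± 0.014, SE, adjusted p = 0.00188) and chromosome 16 from 69000001 to 70000000, with no named gene (-0.11 ± 0.02, adjusted p = 0.0127). The latter was not called with medians over probes (-0.07) or with mean minus background signal (-0.093). Each of these last windows holds 1 probe that read 0.95 or 1.04 on the control array and between -0.43 and -0.086 on the knockdown arrays. With medians over probes, the difference of the window on chromosome 15 stayed at -0.113, so this 1 probe alone does not set it.

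Of 8740 genes, 681 were called between the groups, 626 higher and 55 lower in the knockdown. Higher genes lay mostly on chromosomes 13 (235 of 337 tested), 5 (174 of 573), 4 (94 of 564), 12 (62 of 329), 19 (23 of 258) and 14 (19 of 322). Most gene calls stood close to the threshold. An adjusted p under 0.01 left 3 genes, all lower: Arhgap40 (-0.51 ± 0.022, SE), Bfsp1 (-0.63 ± 0.033) and Wnt11 (-0.55 ± 0.024), which were chosen after their values were seen. In Bfsp1 and Wnt11 1 probe carried the difference, and in Arhgap40 2 of 3 probes. Gene medians gave 117 calls, and a minimum size of 0.2 gave 64. With genes of a single probe included, limma called 0 of 18702, with 3491 at an unadjusted p under 0.05 and a lowest adjusted p of 0.108.

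By list, 2 of 16 amplified oncogenes were called higher in the knockdown, Cdk8 (0.10 ± 0.021, SE, adjusted p = 0.0417) and Pdgfra (0.11 ± 0.023, adjusted p = 0.0486). Of 20 genes of repair, mitosis and cohesin, Brca2 (0.21 ± 0.025, adjusted p = 0.0229) and the spindle checkpoint gene Mad1l1 (0.11 ± 0.019, adjusted p = 0.0335) were called higher. Of 17 tumour suppressors, Brca2 and the hedgehog receptor gene Ptch1 (0.15 ± 0.021, adjusted p = 0.0246) were called. Of 21 fragile-site genes, Dab1 (0.19 ± 0.019, adjusted p = 0.0212) and the cAMP phosphodiesterase gene Pde4d (0.14 ± 0.019, adjusted p = 0.0244) were called. Of 10 strain-variable loci, the mitochondrial transhydrogenase gene Nnt (0.15 ± 0.021, adjusted p = 0.0246) was called. Each of these lies on chromosome 4, 5 or 13 within the changes above. Adjusted over the list alone, the counts were the same except for 2 strain-variable loci.

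The call of Cdk8 was lost without knockdown replicate 1, 2 or 3 (adjusted p = 0.0565, 0.0666 and 0.0644; range over alternatives 0.0169 to 0.178). Those of Pdgfra (0.0952 and 0.0772; range 0.0228 to 0.17) and Mad1l1 (0.0698 and 0.0559; range 0.0123 to 0.152) were lost without replicate 2 or 3. With medians over probes, the calls of Nnt, Pde4d and Ptch1 were lost as well, at differences of similar size (0.1572, 0.1275 and 0.1281) with adjusted p of 0.0549, 0.0707 and 0.0862. Without an array, the differences also stayed similar in size for Cdk8 (0.104, 0.110 and 0.0972), Pdgfra (0.0998 and 0.106) and Mad1l1 (0.107 and 0.102). With mean minus background signal, the calls of Cdk8 and Pdgfra were lost too. None of the 10 heterochromatin genes, the 23 intestinal tumour genes or the paralog Kmt5b was called by limma. The largest heterochromatin difference was that of the maintenance methyltransferase gene Dnmt1, at -0.09 ± 0.029 (adjusted p = 0.131), which passed only without knockdown replicate 1 (-0.11, adjusted p = 0.0433; range 0.0433 to 0.358). Dnmt3a, at 0.08 ± 0.019 (adjusted p = 0.0564), was called only with normexp (0.1248, adjusted p = 0.0355; range 0.0231 to 0.192). The largest intestinal tumour gene difference was that of Tgfbr2, at 0.06 ± 0.023 (adjusted p = 0.193). Apc differed by -0.0097 ± 0.019. Nlrp1b, at 0.21 ± 0.055 (adjusted p = 0.0794), passed without any 1 knockdown array (adjusted p = 0.0255, 0.0493 and 0.0496; range 0.0255 to 0.985), though 4 of its 6 probes had almost no organoid signal.

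Counted per array, altered segments numbered 48 in the control (38 gains, 10 losses) and 49, 60 and 69 in knockdown 1, 2 and 3. They covered 12.2% of the genome spanned by probes in the control and 12.1%, 12.1% and 12.2% in the knockdown arrays. This rests on the minimum amplitude of 0.2: with 0.15, and adjoining segments joined, the cover was 17.3% in the control, with 21 losses, and 12.3%, 12.4% and 13.1% in the knockdown arrays, with 12, 11 and 19 losses. Chromosomes 5, 12 and X held 36 of these segments in the control and 40, 53 and 60 in the knockdown arrays, so the count mainly tells into how many pieces the large gains were divided. With adjoining segments joined, an alternative chosen after seeing the data, the counts were 23, 33, 28 and 31. A split threshold of 5 moves each count of segments by over 1.5 times, as normexp does in the control and knockdown 2. The counts were not tested between groups.

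Suv4-20h2 acts in pericentric and telomeric heterochromatin, and the chromosome ends nearest to these were compared. The first 5 Mb of probes on each autosome (6250 probes), next to the centromere in mouse, lay -0.0042 ± 0.0017 (SD, n = 3) from the rest of the autosomes in the knockdown and 0.0083 in the control. The last 5 Mb (7071 probes) lay 0.025 ± 0.0049 and 0.019 from the rest. The differences were -0.013 and 0.006, with exact permutation p of 0.25 and 0.5. The distal difference was 0.0039 log2 without knockdown replicate 3 and 0.012 with ends of 2 Mb. Both sets pooled all autosomes, including those with windows called between the groups. Values without these chromosomes were not computed, so the ends are not set apart from those changes. The satellite repeats themselves were not analysed here.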

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

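The joining of adjoining segments was chosen after the data were seen; all other alternatives were planned. No paired analysis was possible because the control was a single array, whose title carries no replicate number. A slide block was not run, since all arrays lay on 1 slide, and the control could not be left out. Dim probes are few, and mainly limit Y and the Nlrp1b region. Of the values that answer a comparison, 185 of those recomputed stayed within their limits and 53 moved; leaving out a knockdown array moved none of them beyond these limits. Of 874 values of 26 named genes, 820 kept their call, 44 lost it, 8 gained it and 2 turned direction. Probe means of named regions and loci were compared by size alone, and 46 of them moved. Where no reason is given, the cause was not tested.

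Called windows between the groups, 201, became 313 with normexp, 414 with 0.5 Mb windows, 94 with 2 Mb windows, 514 with no size minimum and 4 with a minimum of 0.2. Windows against kidney, 506, became 1054, 232, 1925 and 302 for the last 4 of these. Window sizes change the number of windows tested, and size minimums change what counts as a call. Genes between the groups, 681, became 117 with gene medians, 0 with genes of 1 probe, 64 with a minimum of 0.2 and 3 with an adjusted p under 0.01. Genes against kidney, 1791, became 5648 with genes of 1 probe, 992 with at least 5 probes, 4953 with no size minimum and 1044 with a minimum of 0.2.

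Altered segments became 94 in the control and 111 in knockdown 2 with normexp. A split threshold of 5 gave 93 in the control and 74, 99 and 107 in knockdown 1, 2 and 3; a threshold of 8 gave 29 in the control and 28 and 33 in knockdown 1 and 2. Joining gave 23 in the control and 28 and 31 in knockdown 2 and 3.

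Chromosome differences with normexp were 0.11 on 5, 0.093 on 12 and 0.133 on 13, and with mode centring 0.061 on 4, 0.094 on 5, 0.082 on 12 and 0.127 on 13. Knockdown levels against kidney were 0.627 on 5, 0.607 on 12, 0.222 on X and -1.42 on Y with normexp, and 0.541, 0.524 and 0.183 on 5, 12 and X with mode centring. Medians over probes gave 0.546, 0.528, 0.0017 and -4.12 on 5, 12, X and Y; on X most probes lie outside the gain. Mean minus background signal gave 0.163 on X and -4.42 on Y, and probes well above background on all arrays gave -3.11 on Y, where this filter removes the lowest probes. The pericentric difference was -0.015 with normexp and -0.0091 with ends of 2 Mb, and the distal one 0.012 with ends of 2 Mb. Tgfbr2 (0.072) and Cd244a (0.022) against kidney turned direction with gene medians, which a few low probes do not move.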

Other observations

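The 11 tests of explanations in this part were all chosen after the results they concern were seen; the short loci come from the planned segments with the joining of adjoining segments, an alternative also added then. Besides Wwox and Nlrp1b, short altered loci on all 4 arrays were few. A loss in the receptor phosphatase gene Ptprg, on chromosome 14 from 12375884 to 12421718 (7 probes), stood at -0.70 in the control and -0.92 ± 0.059 (SD, n = 3) in the knockdown. A gain inside Pde4d, on chromosome 13 from 110119004 to 110178398 (7 probes), stood at 0.42 and 0.54 ± 0.029. Losses at Btaf1 (chromosome 19 from 36991243 to 37039524, 6 probes; -0.66 and -0.61 ± 0.028) and at Ide (37304480 to 37439851, 12 probes; -0.52 and -0.53 ± 0.019) lay close together. In all, 12 short loci were found, 9 losses and 3 gains, 7 of them on all 4 arrays, 1 on 3 arrays and 4 on 1 array. Among those called on knockdown arrays alone was a gain at Sfi1 in knockdown 1, on chromosome 11 from 3039693 to 3074178. Its mean was 0.39 in the control and 0.30 ± 0.068 in the knockdown. All 4 arrays lay above the limit of 0.2 there, so only the segment call was particular to knockdown 1. The other, in knockdown 3, was a loss inside the lower region of chromosome 19 (57162427 to 58628917). It stood at 0.091 in the control and -0.196 ± 0.0080 in the knockdown, where all 3 arrays lie close to the limit of 0.2. The 2 in the control alone were a loss at Elavl2, a neuronal RNA-binding protein gene (chromosome 4 from 89910434 to 92086996; -0.23 in the control and -0.075 ± 0.025), which is a part of the region of chromosome 4 that lay lower in the control, and a gain at Tubgcp5 (chromosome 7 from 63046527 to 63091060; 0.28 and 0.16 ± 0.048).

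Single probes, a comparison also chosen after the data were seen, parted too. Of 170115 probes outside Y, 51 were lower in every knockdown array than in the control by at least 1 log2 unit and 0 were higher. With knockdown 3 as the lone array instead, 65 probes were lower and 7 higher in the other 3 arrays, with knockdown 1, 14 and 3, and with knockdown 2, 0 and 2. Among the 51 were a probe in Bfsp1 (-0.67 in the control, -2.96, -3.04 and -3.37 in the knockdown), a probe in Wnt11 (0.23 against -1.31, -1.31 and -1.46) and a probe in Arhgap40 (1.16 against -0.072, 0.059 and 0.031). Like the probe in Arhgap40, many of the 51 read high in the control and near kidney level in the knockdown. A probe in Nr4a3 did so, at 2.22 against -0.17, -0.097 and -0.38.

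The control array showed smaller gains of chromosomes 5 and 12 and lower values on chromosome 13 and the region of chromosome 4. Normal cells with 1 copy of X mixed into the control would shorten every gain. Yet the share of the control lacking the gain of X was -0.703% (95% bootstrap interval -1.79 to 0.328), against 20.4% (19.90 to 20.99) for chromosome 5. Ratios compressed towards 0 would not put chromosome 13 at -0.136 relative to the unaltered autosomes, where the knockdown lies at -0.0039. Both values argue against these explanations. Normal female cells, with 2 copies of X, would not shorten the gain of X but would raise the rest of X. That rest lay at -0.038 in the control and -0.050 ± 0.0059 (SD, n = 3) in the knockdown. Normal cells of either sex have 2 copies of chromosome 13 and of the region of chromosome 4. Mixed with cells like the knockdown, they would not put these at -0.136 and -0.139 relative to the unaltered autosomes. These values, from the 1 control array, argue against female cells too, which were not tested further. It stays open, as a hypothesis, that a part of the control cells lacked the gains and had 1 copy fewer of chromosome 13 and the region of chromosome 4: the shares it needs were 20.4%, 18.5% (17.86 to 19.15), 17.4% (16.54 to 18.29) and 24.5% (23.47 to 25.49) for chromosomes 5, 12, 13 and 4. They range over 7.09 percentage points and only the intervals of 12 and 13 overlap. These intervals cover the spread between windows and not that between arrays. The shares for 13 and 4 are taken relative to the knockdown, which lay at 1.99 copies on 13 and 2.07 on the region of 4. The control lay at 1.82 copies on both. Whether a single share holds is therefore not decided. An effect of the hairpin also stays open and untested, since 1 array stands for the control. With each of the 4 arrays in turn as the lone one, only the choice of the control called any windows. This cannot decide, since with a knockdown array alone the control joins the group of 3 and widens its spread. Moreover, 4 choices are too few for a share under 0.05.

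Chromosome Y was nearly absent and the first part of X nearly doubled, on arrays labelled male in both channels. Signal levels of different probes depend on the probes as well as on copy number, so their spread was taken from autosomal stretches of as many probes: the SD of the median kidney log2 signal was 0.11 between 1314 stretches of 122 probes and 0.031 between 75 stretches of 1918, while the rest of X lay at -0.896 relative to the autosomes. Failed Y probes are argued against, since the kidney signal on Y exceeded that of single-copy X by 0.0944, within this spread, while the organoid signal was -4.31 relative to it. A lower copy number of the first part of X in the kidney is argued against too, since its kidney signal exceeded the rest of X by 0.0284, within the spread, and the organoid signal did so by 0.95. A male origin with loss of Y and a duplicated part of X cannot be told apart from a female origin with loss of part of an X, because both put the rest of X near 0, as measured (-0.0499 in the knockdown). No test addressed a mislabelled sample.

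Isolated low probes were those at under -0.5 relative to the median of the probes around them, 10 on each side, in the median over the 4 arrays. These probes, on autosomes and outside the short altered loci, gathered near Tgfbr2 and Trp53. On chromosome 11 they ran on beyond the 5 Mb around Trp53, with 3 between 75 and 80 Mb and 6 between 80 and 85 Mb, and chromosome 5 held 4 between 10 and 15 Mb. Near these genes, 78.6% of the low probes of knockdown 1 were also low in the control. This does not decide on noise, since these places stood out by probes low in the median over all 4 arrays. Over all autosomes, 35.9% of the low probes of knockdown 1 were also low in the control, against 0.089% of all autosomal probes. That recurrence argues against noise of single probes as the source of all low probes. DNA of another mouse strain around a gene, where sequence differences weaken binding, and small deletions cannot be told apart here. The share of low probes does not decide, since it is the pattern itself: 2.34% of probes within 5 Mb of Tgfbr2 (17 of 726) and 1.32% near Trp53 (11 of 834) were low, shares that 0.07% and 0.75% of 10000 random intervals reached. Near Apc the share was 0 (0 of 742), as in the median random interval, which leaves a short stretch of such DNA open there. The labels do not state which genes were altered to make these organoids.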
